A study of Schmidtea mediterranea with 24 samples.

How the data were processed

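The series measured polyadenylated RNA in the asexual planarian flatworm Schmidtea mediterranea (strain CIW4) by RNA sequencing. Gene expression was knocked down by RNA interference (RNAi), in which animals were fed liver containing in vitro transcribed double-stranded RNA (dsRNA). Per the labels, 6 control and 6 myoD RNAi animals received 10 feedings in 7 weeks, and 5 control and 7 nkx1-1 RNAi animals received 12 feedings in 9 weeks. Control animals were fed dsRNA of unc-22, a gene of the nematode Caenorhabditis elegans. The title, the design text and the tissue label describe individual intact animals, 1 library per animal. The extraction text of the same records instead speaks of pooled wounds from tail fragments. The libraries are treated here as individual intact animals, since 3 label fields say so and the extraction text alone differs. If that reading is wrong, the replicate spread would not be a spread between single animals.

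Libraries were made with a stranded mRNA kit, per the labels' protocols. Per the submitters' processing notes, CASAVA, cutadapt 1.8, Bowtie 1.1.1, SAMtools and DESeq were used, and those notes give no role or order. Alignment settings and the strand setting of the counting are not given in the sources used here. The features are contigs of a transcript assembly, named in the ID column with the prefix dd_Smed_v4, so no genome build, chromosome or coordinate applies. The deposited files do not pair contig IDs with gene names, and no other table of names was used here. The level of the targeted genes, the planned lists of muscle, positional, neoblast, epidermal, neural, intestinal, protonephridial and other markers, and any statement about gene families were therefore not run. Contigs of similar sequence can share reads, and a contig can be part of a gene, so each value below belongs to a contig.

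The authors deposited whole-number read counts per contig for all 24 libraries, without normalization. The table holds 26563 contigs, of which 290 had no count in any library, and the IDs fall into 26402 components. The authors also deposited a table for each RNAi group against its own control. Per the file headers, these tables give size-factor-normalised means (a signal value for the pair and for each group), a linear fold change (the ratio of the RNAi mean to the control mean), its log2, a p-value and an adjusted p-value. The deposited ratio was checked against the deposited means and matched them within a relative difference of 6.17e-09. In the myoD table the log2 column holds a spreadsheet error text in 291 cells where the ratio is 0, so log2 values were taken from the ratio column there. In the nkx1-1 table the deposited log2 column held log2 of the deposited ratio.

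Counts were tested with edgeR 4.0.16 in R 4.3.3. Contigs with low counts were removed with the default filterByExpr settings, libraries were scaled by TMM factors, and the quasi-likelihood F test (glmQLFit and glmQLFTest, without robust estimation) was applied. Adjusted p-values are Benjamini-Hochberg values over the contigs tested in that comparison, and contigs under 0.05 are called. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the F statistic. Each RNAi group was fitted with its own control alone, on 12 libraries. The difference of both RNAi effects was tested as a contrast in a fit of all 24 libraries with 4 groups. The controls of both schedules were compared on 11 libraries. All p-values are two-sided. Shared calls were tested with Fisher's exact test for each combination of directions. Values per contig are TMM-scaled CPM (counts per 1e6 counts of the library). Principal components were computed on log2 CPM (prior count 2) of the 500 most variable contigs. The spread between animals was the root mean square distance of a library's log2 CPM profile from the mean of the other libraries of its group, over the 500 most variable contigs of the pair, and was compared with an exact permutation test.

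Groups, tests and alternatives were fixed before the data were examined. So was the rule for naming contigs, which requires an adjusted p under 0.05, no overlap in CPM between the RNAi and control libraries, and a mean over the pair of at least 1 CPM. The contigs with the largest log2 fold changes were then taken, 2 higher and 2 lower in each RNAi comparison, because no names were at hand. Other contigs are described as counts.

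Total counts ranged from 9757113 to 18136698 per library, with a median of 14999872. No pair of libraries within a group was identical within sampling noise: the chi-square per degree of freedom over contigs with at least 10 counts in the pair was 4.18 to 103. Each fit was tested on simulated counts with known changes, drawn from the means and totals of the real libraries. In the myoD simulation over 16352 contigs, 76.1% of contigs changed 1.5-fold, 95.5% of those changed 2-fold and 98.5% of those changed 4-fold were recovered. For the nkx1-1 simulation over 16598 contigs these shares were 74.6%, 91.0% and 98.5%. For the difference of effects over 17159 contigs they were 56.7%, 88.1% and 95.5%, and for the controls over 16262 contigs 76.1%, 94.0% and 97.0%. False calls made up 8 of 188, 9 of 185, 14 of 174 and 14 of 192 calls in these simulations. Each recovered share rests on 66 or 67 changed contigs. The simulated contigs varied independently, without a difference between schedules or a library set apart. The shares may therefore not hold for the real libraries.

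Alternatives were DESeq2 size factors in place of TMM, no filter and a filter at 1 CPM, the DESeq2 1.42.0 Wald test, limma 3.58.1 voom with quality weights, robust estimation, a joint fit, the replicate number as a block, counts summed per component, a 2-fold minimum, and leaving out each library in turn. After the data had been seen, fits without 2 libraries that stood apart from their groups were added. The settings planned for both RNAi comparisons were also applied to the shared calls, nkx1-1 RNAi was compared with its controls on replicates 1 to 5 alone, and the spread was recomputed on 1000 contigs, with the other size factors and with each library left out.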

Results

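Whole uninjured planarians were profiled after weeks of RNAi against either of 2 transcription factors, to measure expression during ordinary tissue turnover. MyoD and nkx1-1 encode transcription factors needed in planarians for body-wall muscle, with myoD required for longitudinal fibres and nkx1-1 for circular fibres. The design sets 6 myoD RNAi animals against 6 controls after 10 dsRNA feedings in 7 weeks, and 7 nkx1-1 RNAi animals against 5 controls after 12 feedings in 9 weeks. Each library is 1 animal, as the design text and tissue label give it. Total counts averaged 14752834 ± 1361757 (SD, n = 6) in the 10-feeding controls and 15322710 ± 1475292 (SD, n = 6) after myoD RNAi. They averaged 15965226 ± 1332270 (SD, n = 5) in the 12-feeding controls and 14532781 ± 2525553 (SD, n = 7) after nkx1-1 RNAi, with the lowest total, 9757113, in nkx1-1 RNAi replicate 2. The contig with the most counts over all libraries took 6.60% to 10.1% of the counts of a library.

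Across all 24 animals the main axis of variation ran between the animals of the 2 feeding schedules, with 1 exception. Number of feedings, time and cohort go together in these schedules. The principal component with the largest share of variance, 52.5%, placed the 12 animals of the 10-feeding schedule between 11.4 and 19.8. It placed 11 of the 12 animals of the other schedule between −25.5 and −10.2. The exception was replicate 3 of the 12-feeding controls, at 10.8. The next component, with 11.8% of the variance, placed the 10-feeding controls at 2.51 to 12.1 and the myoD RNAi animals at −13.0 to −1.73, without overlap. It placed the 12-feeding controls at 4.08 to 10.7 and the nkx1-1 RNAi animals at −9.89 to 4.30, where only nkx1-1 RNAi replicate 3 reached the control range. Another library that stood apart was nkx1-1 RNAi replicate 1, in which the contig dd_Smed_v4_4_1_1, singled out after its values were seen, took 6.79% of the counts, against 0.0393% to 0.391% in the other nkx1-1 RNAi animals.

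**Figure D1:**
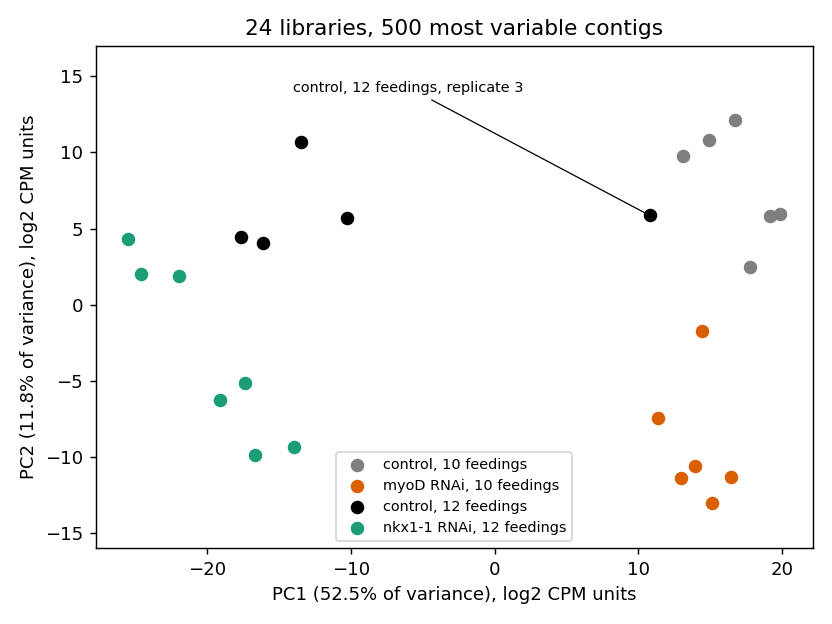
Principal components of the 24 libraries, computed on log2 CPM of the 500 most variable contigs. Each point is 1 animal, coloured by group, the axes are component scores in log2 CPM units with the share of variance given in percent, and the 12-feeding control replicate 3 lies at 10.8 on the horizontal axis while the other controls of its schedule lie between −17.6 and −10.2.

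The comparison of myoD RNAi animals with their controls asked which transcripts change when myoD is inhibited in intact animals. More contigs rose than fell: 844 were higher and 388 lower, together 1232 of the 16352 tested. Most changes were small, with a median size of 0.34 on the log2 scale among called contigs, and 94 of the higher and 17 of the lower contigs changed at least 2-fold. Every myoD RNAi animal lay above every control for 547 of the contigs called higher and below every control for 194 of those called lower. Calling itself favours such contigs. Among all 16352 tested contigs, called or not, 794 had no overlap, where chance gives 0.216% in both directions together. Among the contigs that rose and passed the naming rule, dd_Smed_v4_17217_0_1 changed most. It went from 0.181 ± 0.0708 CPM (SD, n = 6 controls) to 2.80 ± 0.874 CPM (SD, n = 6), a log2 fold change of 3.88 ± 0.31 (SE) with an edgeR adjusted p of 1.80e-07. It rested on 1 to 4 counts per control library and 32 to 57 per RNAi library. The contig dd_Smed_v4_11785_0_1 rose from 0.346 ± 0.253 to 2.82 ± 0.672 CPM (SD, n = 6 each), a log2 fold change of 2.98 ± 0.30 (SE; edgeR adjusted p = 3.97e-06).

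Of the contigs that passed the naming rule, dd_Smed_v4_12634_0_1 fell deepest after myoD RNAi, from 10.9 ± 0.723 CPM in controls to 0.498 ± 0.315 CPM (SD, n = 6 each). Its log2 fold change was −4.39 ± 0.18 (SE), which leaves 0.0478 of the control level, with an edgeR adjusted p of 6.22e-11. Counts for it were 148 to 174 per control library and 3 to 16 per RNAi library. Whether this contig belongs to the targeted gene is open, because no names were at hand. The contig dd_Smed_v4_18181_0_1 fell from 4.91 ± 0.394 to 0.815 ± 0.476 CPM (SD, n = 6 each), a log2 fold change of −2.63 ± 0.22 (SE; edgeR adjusted p = 4.10e-07). In the authors' deposited table these 4 contigs had fold changes of 15.4, 8.14, 0.0456 and 0.165, in the order given here. That table lists 969 contigs under an adjusted p of 0.05, 707 higher and 262 lower. Of the 892 among the tested contigs, 889 were also called by edgeR, all 889 with the same sign, and the log2 fold changes of both sources had a Spearman correlation of 0.999 across contigs. The count fell to 111 (94 higher, 17 lower) when a 2-fold change was also required.

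The comparison of nkx1-1 RNAi animals with their controls asked the same of nkx1-1. It gave 643 called contigs among 16598 tested, 297 higher and 346 lower. The median size of a called change was 0.38 on the log2 scale, and 45 higher and 7 lower contigs changed at least 2-fold. All RNAi animals lay above all controls for 117 of the contigs called higher and below them for 203 of those called lower. Among all 16598 tested contigs, called or not, 469 had no overlap, where chance gives 0.253% in both directions together. The contig that passed the naming rule with the largest rise was dd_Smed_v4_19327_0_1, which went from 2.44 ± 0.292 CPM (SD, n = 5 controls) to 110 ± 36.0 CPM (SD, n = 7). This is a 45.2-fold increase, 5.50 ± 0.25 (SE) on the log2 scale, with an edgeR adjusted p of 3.21e-09, and the RNAi animals ranged from 75.2 to 175 CPM against 2.17 to 2.90 CPM in controls. The contig dd_Smed_v4_19966_0_1 rose from 0.453 ± 0.205 (SD, n = 5) to 1.52 ± 0.402 CPM (SD, n = 7), a log2 fold change of 1.76 ± 0.29 (SE; edgeR adjusted p = 0.00519).

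Among contigs that fell after nkx1-1 RNAi, dd_Smed_v4_15058_0_1 went from 1.89 ± 0.408 (SD, n = 5) to 0.514 ± 0.129 CPM (SD, n = 7), a log2 fold change of −1.85 ± 0.20 (SE; edgeR adjusted p = 0.000270). The abundant contig dd_Smed_v4_2786_0_1 fell from 211 ± 45.8 (SD, n = 5) to 102 ± 33.2 CPM (SD, n = 7), a log2 fold change of −1.05 ± 0.19 (SE; edgeR adjusted p = 0.00870). The authors' deposited table gave fold changes of 45.1, 3.33, 0.271 and 0.484 for these 4 contigs in the order given here. It lists 430 contigs under an adjusted p of 0.05, 200 higher and 230 lower. Of the 419 among the tested contigs, edgeR also called 395, all 395 with the same sign, and the log2 fold changes had a Spearman correlation of 0.998 across contigs. At an adjusted p of 0.1 in both sources, 634 were shared.

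The number of contigs called after nkx1-1 RNAi depended on the libraries and on the test. It was 325, 214 and 391 without 12-feeding control replicate 2, 4 or 5, and 412, 352, 332 and 391 without nkx1-1 RNAi replicate 4, 5, 6 or 7. Without nkx1-1 RNAi replicate 1 alone 947 were called, and rises then outnumbered falls, 519 to 428. Without 12-feeding control replicate 3 and nkx1-1 RNAi replicate 1, the 2 libraries that stood apart, 748 contigs were called, 436 higher and 312 lower. DESeq2 called 1042, voom with quality weights 976, the joint fit of 24 libraries 1849, a fit on replicates 1 to 5 of both groups 133, and 52 passed with a 2-fold minimum.

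**Figure D2:**
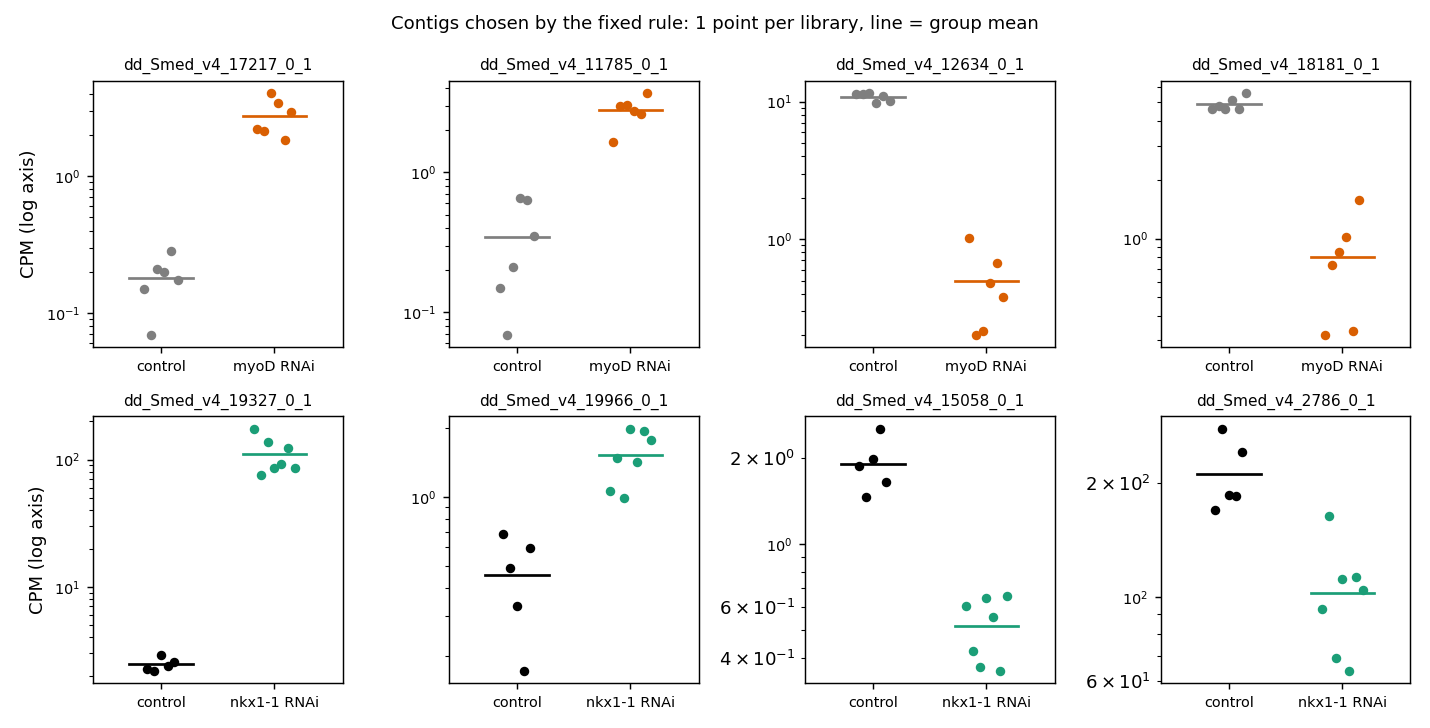
Levels of the 8 contigs named by the fixed rule, in TMM-scaled CPM on log axes, with 1 point per animal and a line at each group mean. CPM was scaled here over all 24 libraries, so values differ slightly from those scaled within a pair. The upper row shows 6 controls and 6 myoD RNAi animals, the lower row 5 controls and 7 nkx1-1 RNAi animals. No RNAi point overlaps the controls, as the naming rule required, and dd_Smed_v4_19327_0_1 lies at 75.6 to 176 CPM against 2.19 to 2.91 CPM.

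Many of the same contigs changed under both RNAi treatments, each measured against its own control animals. Of 16162 contigs tested in both comparisons, 832 were higher after myoD RNAi and 284 after nkx1-1 RNAi, and 191 were higher in both, where independent lists would share 14.6. The odds ratio was 48.8 (95% confidence interval 37.4 to 63.9; Fisher's exact p = 1.47e-181, adjusted over 4 combinations 5.89e-181). Of 387 and 345 lower contigs, 58 were lower in both against 8.26 for independent lists, with an odds ratio of 9.51 (6.90 to 12.9; Fisher's exact p = 1.42e-32, adjusted 2.83e-32). Opposite calls were fewer than independent lists would give. Higher after myoD and lower after nkx1-1 RNAi were 5 contigs against 17.8 (Fisher's exact p = 0.000491, adjusted 0.000655), dd_Smed_v4_2786_0_1 among them, and the reverse was found for 0 contigs against 6.80 (Fisher's exact p = 0.00237, adjusted 0.00237). Contigs are not independent replicates, so these p-values describe the lists and not a spread between animals.

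Contigs higher in both had median log2 fold changes of 0.57 after myoD and 0.50 after nkx1-1 RNAi, and those lower in both −0.32 and −0.35. Of the contigs called higher after myoD RNAi, 90.1% had the same sign after nkx1-1 RNAi, and of those called lower, 87.3%. In the other direction these shares were 89.1% and 80.9%. All of these shares include contigs called in both comparisons. Of the 965 contigs called only in the myoD comparison 86.9% had the same sign, and of the 375 called only in the nkx1-1 comparison 75.5%. Contigs called lower after nkx1-1 RNAi had a Pearson correlation of 0.063 between both log2 fold changes, against 0.648 for those called higher. For contigs called higher and lower after myoD RNAi it was 0.742 and 0.364. Over all 16162 contigs the share with the same sign was 58.8%, and over the 14568 called in neither comparison 55.9%. Across the 16162 contigs, the log2 fold changes had a Pearson correlation of 0.441 and a Spearman correlation of 0.279. Both contigs named for their rise after myoD RNAi also rose after nkx1-1 RNAi: dd_Smed_v4_17217_0_1 by 2.26 ± 0.47 (SE; edgeR adjusted p = 0.0172) and dd_Smed_v4_11785_0_1 by 2.63 ± 0.44 (SE; edgeR adjusted p = 0.00542) on the log2 scale. In nkx1-1 RNAi replicate 1, 1 of the libraries that stood apart, both stayed within the range of the controls: 0.303 CPM for dd_Smed_v4_17217_0_1 (below 4 of the 5 controls, other nkx1-1 RNAi animals at 1.11 to 3.02) and 0.454 CPM for dd_Smed_v4_11785_0_1 (controls 0.173 to 0.876, others 1.97 to 3.92). These CPM values of single libraries were scaled over all 24 libraries. In turn, dd_Smed_v4_19966_0_1 rose by 1.85 ± 0.21 (SE; edgeR adjusted p = 1.04e-05) after myoD RNAi.

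The number of contigs higher in both was 97 and 78 without 12-feeding control replicate 2 or 4, and 122, 106 and 112 without nkx1-1 RNAi replicate 4, 5 or 6. It was 314 without nkx1-1 RNAi replicate 1, and 297 without this library and 12-feeding control replicate 3. Those lower in both fell to 26 without 12-feeding control replicate 4, and numbered 50 without the 2 libraries that stood apart. With DESeq2 287 were higher and 95 lower in both, and with the joint fit 352 and 95. Voom with quality weights gave 296 higher in both, and an unadjusted p under 0.01 gave 363 and 156. With a 2-fold minimum in both comparisons 26 were higher and 1 lower in both, against 0.185 and 0.00594 for independent lists.

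**Figure D3:**
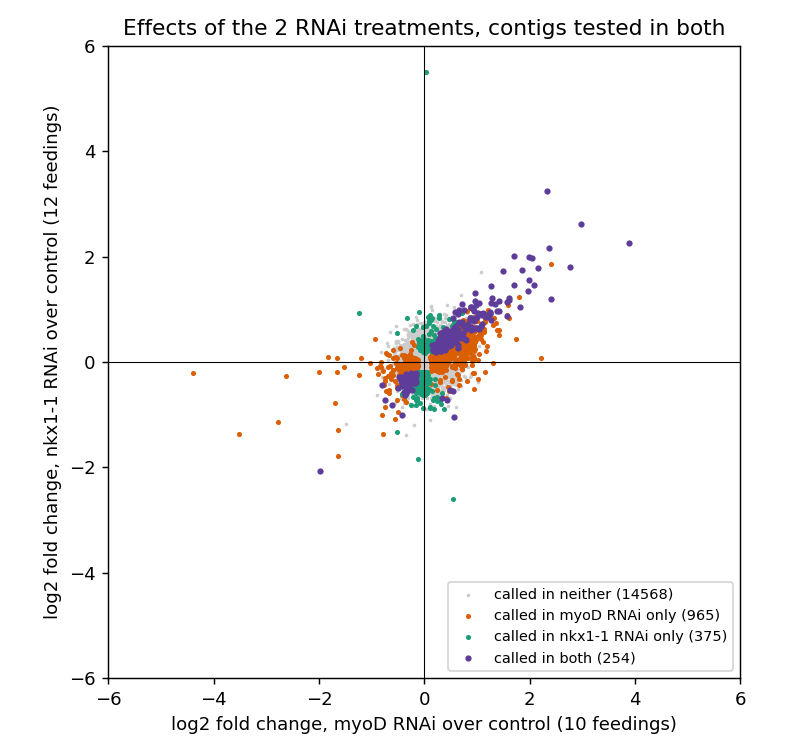
Log2 fold change after nkx1-1 RNAi against log2 fold change after myoD RNAi, 1 point per contig tested in both, each over its own controls, coloured by the comparison in which the contig was called. The 191 contigs higher in both spread along the upper right, and the isolated point near the top is dd_Smed_v4_19327_0_1 at 5.50 after nkx1-1 and 0.04 after myoD RNAi.

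Whether the effects of both treatments differed was tested directly on all 24 libraries. The effect differed for 73 of 17159 contigs, with a more positive nkx1-1 effect for 29 and a more negative one for 44. Of these 73, 30 had been called only in the myoD comparison, 32 only in the nkx1-1 comparison and 7 in both, 5 of them in opposite directions. Both contigs named for their fall after myoD RNAi were among the 73. For dd_Smed_v4_12634_0_1 the nkx1-1 value was −0.20 ± 0.09 (SE; edgeR adjusted p = 0.235), and the difference of effects was 4.19 ± 0.22 (SE; edgeR adjusted p = 4.61e-13). For dd_Smed_v4_18181_0_1 the difference was 2.37 ± 0.27 (SE; edgeR adjusted p = 4.84e-06).

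The large rise of dd_Smed_v4_19327_0_1 after nkx1-1 RNAi had no counterpart after myoD RNAi, where its value was 0.04 ± 0.19 (SE; edgeR adjusted p = 0.951), and the effects differed by 5.47 ± 0.39 (SE; edgeR adjusted p = 5.67e-10). The fall of dd_Smed_v4_15058_0_1 differed by −1.71 ± 0.34 (SE; edgeR adjusted p = 0.0153). For dd_Smed_v4_2786_0_1, which rose by 0.56 ± 0.12 (SE; edgeR adjusted p = 0.00713) after myoD RNAi, it was −1.59 ± 0.25 (SE; edgeR adjusted p = 0.00113). No difference was called for dd_Smed_v4_17217_0_1, dd_Smed_v4_11785_0_1 or dd_Smed_v4_19966_0_1 (edgeR adjusted p = 0.337, 0.868 and 0.955). The targeted gene goes with the number of feedings, the weeks of treatment and the cohort, which cannot be told apart from it here. The count of 73 became 48, 48 and 46 without 12-feeding control replicate 4, 10-feeding control replicate 5 or myoD RNAi replicate 3, and 132 and 136 without nkx1-1 RNAi replicate 1 or 2. It was 104 without 12-feeding control replicate 3 and nkx1-1 RNAi replicate 1, 156 with DESeq2 and 130 with voom.

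More contigs were called between the controls of both schedules than between either RNAi group and its control. Between 12-feeding and 10-feeding controls, 5701 of 16262 contigs were called (35.1%), 2965 higher and 2736 lower in the 12-feeding animals. These changes were small too, with a median size of 0.35 on the log2 scale, and 84 higher and 48 lower contigs changed at least 2-fold. Without 12-feeding control replicate 3, 6963 contigs were called, 3511 higher and 3452 lower. Number of feedings, time and cohort cannot be told apart in this comparison, and each RNAi group is therefore read only against the controls of its own schedule.

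No difference was found between RNAi and control animals in how much they varied among themselves. The mean distance of an animal from the others of its group was 0.610 ± 0.149 log2 units (SD, n = 6) after myoD RNAi and 0.689 ± 0.128 (SD, n = 6) in controls. The difference of −0.0788 was within the spread (two-sided exact permutation p = 0.362, adjusted over 2 comparisons 0.723). After nkx1-1 RNAi the distance was 0.866 ± 0.223 (SD, n = 7) against 0.887 ± 0.276 (SD, n = 5), a difference of −0.0206 (two-sided exact permutation p = 0.897, adjusted 0.897). A mean over fewer other libraries is noisier, which by itself lengthens the distances in the group of 5. The permutations exchanged the distances without recomputing them, so the p-values of both pairs are approximate. The control value includes 12-feeding control replicate 3, whose distance of 1.38 exceeded the 0.735 to 0.787 of the other controls of its group. Without that library the sign of the difference turned, to 0.147 (two-sided exact permutation p = 0.249), and it also turned without nkx1-1 RNAi replicate 4 (0.0624) or 6 (0.0188), so the comparison gives no direction.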

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

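In this part, the score of nkx1-1 RNAi animals on myoD-responsive contigs, the tests of a wrong label, of low depth and of a mixed library, and the 3 tests on dd_Smed_v4_19327_0_1 were chosen after the results had been seen. So was the contig dd_Smed_v4_4_1_1 in the gap tests.

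Gap tests within groups singled out 6 of 48 sets of values, where chance gives about 1 in 20 sets, or 2.4. The 6 cannot be read as an excess over 2.4. The contig dd_Smed_v4_4_1_1 was included because its values stood out, and 2 of the 6 concern the same library. The total of 10-feeding control replicate 6 was 17375822 counts, against 13597429 to 14981573 in the rest of its group. The contig with the most counts over all libraries took 7.90% of counts in myoD RNAi replicate 2 and 9.38% to 10.1% in the other myoD RNAi animals. In nkx1-1 RNAi replicate 1 the contig dd_Smed_v4_4_1_1 held 6.79% of counts, against 0.0393% to 0.391% in the other animals of the group. On the second-largest component, 12-feeding control replicate 4 lay at 10.7 and the other controls of its schedule at 4.08 to 5.86. Of the 6, 2 concern 12-feeding control replicate 3, which lay at 10.8 on the main component (others −17.6 to −10.2) and at a distance of 1.38 from its group (others 0.735 to 0.787). Effects of both treatments differed by test for 5 named contigs, nkx1-1 minus myoD on the log2 scale: dd_Smed_v4_12634_0_1 by 4.19, dd_Smed_v4_18181_0_1 by 2.37, dd_Smed_v4_19327_0_1 by 5.47, dd_Smed_v4_15058_0_1 by −1.71 and dd_Smed_v4_2786_0_1 by −1.59.

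The animals were also split in other ways, 100 splits for each comparison with the real one included, to see whether chance can be excluded. For myoD RNAi 1 of 100 splits, the real one, reached 1232 calls, and the highest other gave 255. For nkx1-1 RNAi 1 of 100 reached 643 and the highest other gave 542, so chance is excluded by a narrower distance. That other split set nkx1-1 RNAi replicates 3 to 7 against all 5 controls with nkx1-1 RNAi replicates 1 and 2, so it still kept much of the real contrast. For the difference of effects 2 of 100 splits reached 73, the real one included. Its highest other gave 272, several times the real count. That split kept the real myoD and 10-feeding control labels and exchanged 3 controls with 3 nkx1-1 RNAi animals, so it set the whole myoD effect against a mixed 12-feeding contrast, and no other structure among the animals was tested. Most other splits also broke up the myoD groups, so they show what no effect of either treatment would give and leave open whether the 73 exceed chance. For the controls 1 of 100 reached 5701 and the highest other gave 3283. Chance is thus excluded at a share of 0.05 for the myoD, nkx1-1 and control counts, which says nothing of what else divides the animals.

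Contigs higher under both treatments numbered 191, where independent lists would share 14.6. A tendency to call abundant contigs in both does not account for this, since 1000 draws that kept the abundance of the called contigs shared at most 29. A chance position of the 12-feeding animals along an axis that also varies among controls is left undecided. On the 832 contigs higher after myoD RNAi, 7 of 7 nkx1-1 RNAi animals scored above the highest of 5 controls. Replicate 1 did so narrowly (−0.103 against −0.119, the other 6 at 0.0598 to 0.213). The mean difference was 0.292 on the log2 scale (two-sided exact permutation p = 0.00253, adjusted over 4 scores 0.00253). This score cannot decide, since 191 of the 832 contigs had already been called higher in these same animals. On this score the 5 controls spread from −0.207 to −0.119 (SD 0.0461), and no score was computed without the 191 contigs. An effect of the unc-22 dsRNA fed to all controls stays open, because the shared contigs had a median change of 0.0593 (quartiles −0.0691 and 0.165) between 12-feeding and 10-feeding controls, and feeding number goes with time and cohort. A common response of intact animals to losing either transcription factor may be at work as well, and the design holds no further target that would test it.

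The 12-feeding control replicate 3 lay between the schedules. A wrongly labelled 10-feeding control is argued against: over contigs separating the other controls, its median position was 0.343 (0 for 10-feeding, 1 for 12-feeding), above the 0.0862 that no held-out 10-feeding control exceeded and below the 0.782 to 1.04 of the others of its group, and low depth is argued against by its total of 15125397 counts, above the 14174155 of replicate 5. A mixture with RNA of an animal like the other 11 of its schedule is argued against by 15 contigs, chosen without reference to it as near absent (at most 3 counts) from all 10-feeding libraries and present (at least 10 counts) in those 11, which summed to 0 counts in it where a mixture at its position would give about 260 at their lowest level; a mixture with a 12-feeding animal lacking them stays open. Lack of these 15 contigs was shared with the 10-feeding animals, which by itself goes with a wrong label. A wrong label is thus argued against by the median position alone. RNA of another organism or of ingested material carried by the 11 other 12-feeding animals is a candidate source of the 15 contigs, beside planarian transcripts that vary between animals. Their median coefficient of variation was 0.392 and abundance-matched sets reached at most 0.223. Their median correlation of 0.304 did not exceed the highest matched value of 0.410. The sets were matched on abundance alone and not on near absence from other animals, so the larger variation does not decide between these sources. Why the rest of the profile of 12-feeding control replicate 3 is displaced, for instance by another culture, size or feeding history, was not tested.

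The rise of dd_Smed_v4_19327_0_1 after nkx1-1 RNAi was not carried by a few animals, as the lowest nkx1-1 RNAi library lay 25.9 times above the highest control. The naming rule already required that the groups not overlap, so only the size of this gap bears on the question. A general response to a test dsRNA is argued against by the difference from the myoD effect, 5.47 on the log2 scale. Sequenced fragments of the fed dsRNA may raise the contig of a targeted gene, and this cannot be told apart from a rise of the transcript, since a 45.2-fold change in counts per contig does not show where the reads lie. Whether the contig belongs to the targeted gene is open too, because the files pair no names with IDs. A true transcriptional response remains a hypothesis beside these.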

How the results depend on the processing

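Chosen after the data were seen were the fits without 12-feeding control replicate 3 and nkx1-1 RNAi replicate 1, the fit on replicates 1 to 5, most settings of the shared calls and all settings of the spread. The targeted-gene and gene-list results were not run, as no names were at hand. Directions of the 8 named contigs held under every setting run. The myoD count stayed within 1.5 times of 1232 except with a 2-fold minimum (111), and was 1023 to 1266 with each library left out. The control count of 5701 stayed within 1.5 times throughout, 4575 to 6963 with each library left out. The nkx1-1 count of 643 was 1042 with DESeq2, 976 with voom, 1849 in the joint fit and 52 with a 2-fold minimum, and 214 to 947 with each library left out. Its lowest values came without 12-feeding control replicates 4 (214) and 2 (325), its highest without nkx1-1 RNAi replicate 1. The 73 differences became 156 with DESeq2 and 130 with voom, and 46 to 136 with each library left out. Contigs higher in both (191) numbered 363 at unadjusted p under 0.01, 287 with DESeq2, 296 with voom, 352 in the joint fit, 26 with a 2-fold minimum and 297 without both libraries that stood apart, and 78 to 314 with each left out. Those lower in both (58) numbered 156 at unadjusted p under 0.01, 95 with DESeq2, 95 in the joint fit and 1 with a 2-fold minimum, and 26 to 74 with each left out. At an adjusted p of 0.1, 634 nkx1-1 calls were shared with the authors' table, against 395. The spread difference was −0.127 to −0.0283 for myoD with each library left out. For nkx1-1 (−0.0206) it was −0.114 to 0.147, with the sign turned without 12-feeding control replicate 3 (0.147), nkx1-1 RNAi replicate 4 (0.0624) or 6 (0.0188), and 0.0899 without both libraries that stood apart; no exact permutation p of these was under 0.05. Except where a looser or stricter threshold explains the change, the cause was not tested.

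No label says that the replicate numbers pair the animals, and correlations of same-numbered deviations gave no clear answer. They were −0.196 to 0.169 for myoD (1 of 6 above 0.1), −0.147 to 0.0156 for nkx1-1 (0 of 5) and −0.0763 to 0.222 for the controls (3 of 5). Their medians were −0.0355, −0.0178 and 0.11, against 0.0142, −0.00031 and 0.00342 for other pairs. The same-numbered animal was the best match in 2 of 6, 0 of 5 and 3 of 5 pairs. So few pairs cannot exclude pairing. With the number as a replicate block, 1115 contigs were called for myoD, 4735 for the controls, 24 for the difference and 12 for nkx1-1, with 5 higher and 1 lower in both. The nkx1-1 block fit holds only replicates 1 to 5, which without a block gave 133. Under the block dd_Smed_v4_19966_0_1 had an adjusted p of 0.127 (range over its settings 2.20e-05 to 0.127) at a log2 fold change of 1.62, against 1.76, and dd_Smed_v4_2786_0_1 of 0.0549 (0.000364 to 0.0549) at −1.14, against −1.05, so neither call was lost by a fold change far from its main value; other named calls kept their side of 0.05. In simulations at the real depth and group sizes, 74.6% of 1.5-fold changes were recovered for nkx1-1 and 76.1% for myoD; depth alone was not varied.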

Other observations

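The 3 scores and the component values in this part were examined only after the results had been seen.

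Lists called in one schedule also separated the animals of the other. These scores include the shared calls and were not recomputed without them, so they are no separate support. In the scored animals themselves, 191 of the 284 and 58 of the 387 or 345 contigs below had already been called in the same direction. The 387 contigs lower after myoD RNAi had a mean score difference of −0.212 on the log2 scale between nkx1-1 RNAi animals and controls, with 7 of 7 below the lowest of 5 controls (two-sided exact permutation p = 0.00126, adjusted over 4 scores 0.00253). The 284 contigs higher after nkx1-1 RNAi scored 0.511 higher in myoD RNAi animals, with 6 of 6 above the highest of 6 controls (two-sided exact permutation p = 0.00217, adjusted 0.00253). For the 345 contigs lower after nkx1-1 RNAi the difference in myoD RNAi animals was −0.101, with 6 of 6 below the lowest control (two-sided exact permutation p = 0.00217, adjusted 0.00253). The 14568 contigs called in neither comparison still had a Pearson correlation of 0.215 between both log2 fold changes, across contigs that are not independent. Called contigs were more abundant than tested ones in both directions. After nkx1-1 RNAi the median was 5.23 log2 CPM for lower and 4.07 for higher contigs against 3.79 for all tested, and after myoD RNAi 4.90 and 4.34 against 3.83.

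The nkx1-1 RNAi animals were spread along the second-largest component. Replicates 1, 3 and 5 lay at 1.89, 4.30 and 2.04, and replicates 2, 4, 6 and 7 at −9.89, −5.17, −6.25 and −9.36. The 12-feeding controls lay at 4.08 to 10.7, so only replicate 3 reached their range and the other nkx1-1 RNAi animals lay below it. No label divides these animals.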
